A study of Mus musculus with 12 samples.

How the data were processed

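RNA from fibroblasts of mouse embryos, wild type or IRAK4 kinase dead, was measured on 12 Affymetrix Mouse Genome 430 2.0 arrays with 1 colour. Per the labels, total RNA was purified with RNeasy columns and amplified and labelled with the NuGEN Ovation method. Per the submitters' processing notes the deposited values are MAS5 signal intensities, 1 value per probe set and array on a linear scale; the version and other settings are not given in the sources used here. The values show that each array was scaled to the same mean of 150 after trimming 2% from each end. The table holds 45101 probe sets, of which 64 are controls. In the platform annotation 34945 probe sets carry 1 gene symbol, 932 carry several and 9160 are not listed with a gene; genes were named from the first kind alone. The gene identifiers of 34754 of these matched the reference table of the mouse assembly GRCm38.p6, which was used only for names and chromosomes.

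Samples were grouped by the titles. The title of wild-type unstimulated replicate 1 does not state the genotype; it was placed by the series design, which gives 6 arrays to each genotype, and leaving it out was one of the alternatives. Both unstimulated groups were grown for 4 h and served as the control for 1 h and 4 h; an unstimulated 1 h group was not analysed here.

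Signals were analysed as log2(signal + 8), where the pseudocount of 8 is the power of 2 nearest to the 25th percentile of all values (7.9). Fold changes are on this scale, which understates changes of low signals. A probe set entered if it reached 25.5, the median of all values, on at least 2 arrays, and each gene was represented by its probe set with the highest mean, which left 12427 genes. Named genes with a call and another tested probe set gave 276 gene and comparison pairs. In 147 of them another probe set was called in the same direction, in 0 in the opposite one, and in 129 no other was called. No further normalization was applied. A linear model with 6 group means (6 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with moderated two-sided tests (eBayes with a trend of variance on mean signal) and Benjamini-Hochberg adjustment within each of 9 comparisons; an adjusted p under 0.05 is called here. The comparison over all conditions used an additive model of condition and genotype. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

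Gene lists (27, with 544 entries, of which 504 matched a gene and 442 were tested) covered IL-1 responsive classes, metabolic and stress programmes, position genes and markers of other cell types. They were tested with camera at a preset correlation of 0.01, adjusted over 243 list and comparison pairs. Of these, 104 were called, 52 of them also with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, called 117. The lists, the design, the alternatives and the rule for named genes were set before the data were examined. That rule takes, per comparison, the 12 largest rises and 8 largest falls among called genes whose arrays separate completely, up to 4 called members of each list that passed or had at least 3 called members, 16 genes named in every comparison, and for the response differences up to 5 genes called in wild-type cells with the largest kinase-dead change. For response differences, the responses over all pairs of arrays had to separate. Over all conditions together, the rule asked instead for the same direction in all 3 conditions. The text names fewer genes than the rule gives. Genes were preferred when leaving out any 1 array did not end their call, a choice made after the values were seen, so the named genes look steadier than the rule's full set. For the response differences the rule gave 31 called genes at 1 h, of which 16 kept the call in all 12 such fits and 15 did not, and 49 at 4 h, of which 32 kept it and 17 did not. In the response at 1 h the rule gave 67 called genes in wild-type cells (22 of them lost in some such fit) and 45 in kinase-dead cells (26 lost), and at 4 h 80 (17 lost) and 39 (22 lost).

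The scripts were tested on simulated data built on the 12427 genes. For the wild-type 1 h comparison 65% of genes changed by 1 on the log2 scale and 92% of those changed by 2 were recovered. For the response difference at 1 h these were 47% and 81%. In those runs 15 of the 177 genes called in the wild-type 1 h comparison, and 5 of the 136 called in the response difference, had not been changed. With no change simulated, 0 genes were called in the wild-type 1 h comparison and 1 in the response difference at 1 h. Actin 3' to 5' signal ratios, a measure of RNA integrity and amplification, were 2.14 to 2.86, with group means of 2.85 ± 0.0178 in unstimulated kinase-dead cells and 2.36 to 2.49 in the others (SD, n = 2). The first principal component held 40.4% of the variance and the next ones 14% and 10.9%. Alternatives covered the pseudocount, the filter, the normalization, the variance model, array weights, the choice of probe set, the arrays in the fit, the replicate number as a block, the call threshold and leaving out each array in turn.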

Results

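Fibroblasts cultured from mouse embryos were compared between wild-type animals and animals carrying a kinase-dead form of IRAK4, the protein kinase that the adaptor MyD88 brings to the activated interleukin-1 receptor. Cells of each genotype were left without stimulation for 4 h, or stimulated with 1 ng/ml interleukin-1 beta (IL-1b), a pro-inflammatory cytokine, for 1 h or 4 h. Each of the 6 groups held 2 arrays, 12 in all. The array medians lay between 23 and 28.3 signal units, and the mean signal, with 2% trimmed from each end, was 150 on each array. Correlations of log2 signals were 0.979 to 0.984 between the 2 arrays of a group and 0.946 to 0.965 on average with arrays of other groups. The series design calls the samples of a group biological replicates without naming separate animals or cultures, so p-values here measure the spread between these samples. The number of arrays limits the precision. The actin 3' to 5' signal ratio, a sign of RNA quality, had a mean of 2.85 ± 0.0178 in unstimulated kinase-dead cells and group means of 2.36 to 2.49 elsewhere (SD, n = 2). The Irak4 transcript was not analysed here, and a label that names lost kinase activity would not be checked by it.

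The first comparison asked which transcripts answered IL-1b within 1 h in wild-type cells. Cxcl2, which encodes a neutrophil-attracting chemokine, went from a signal of 3.70 ± 1.41 to 3927 ± 59.3 (SD, n = 2), a log2 fold change of 8.40 ± 0.16 (SE, n = 2 arrays per group) with adjusted p = 1.31e-15 by limma. Cxcl1, another neutrophil attractant, rose by 6.64 ± 0.25 on the log2 scale, and Ccl2, a monocyte attractant, by 4.55 ± 0.17. Tnfaip3, whose product A20 restrains NF-kB signalling, rose by 5.09 ± 0.14. Fos, a subunit of the transcription factor AP-1, rose by 4.37 ± 0.28.

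Of the 17 chemokines tested in wild-type cells at 1 h, 8 rose, 0 fell and 9 did not pass (8 higher and 0 lower adjusted over the list alone; camera adjusted p = 2.61e-14, and adjusted p = 0.00543 with an estimated correlation). Ccl20 rose by 3.70 ± 0.24, Ccl7 by 3.62 ± 0.16 and Cxcl5 by 3.48 ± 0.25. Of 15 genes for NF-kB subunits and feedback inhibitors, 5 rose, 1 fell and 9 did not pass (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 3.39e-09, and adjusted p = 0.007 with an estimated correlation). Nfkbiz rose by 3.91 ± 0.09, Zc3h12a, which encodes an RNase acting on inflammatory mRNAs, by 3.22 ± 0.38, and Nfkbia, the gene of the inhibitor IkB-alpha, by 2.04 ± 0.11. Of 31 immediate early genes, 23 rose, 0 fell and 8 did not pass (27 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.03e-42, and adjusted p = 0.009 with an estimated correlation). Fosb rose by 3.57 ± 0.48, Ier2 by 3.55 ± 0.28, Zfp36, which encodes a protein that promotes mRNA decay, by 3.32 ± 0.16, and Egr1 by 1.31 ± 0.09. Of 13 survival genes downstream of NF-kB, 6 rose, 0 fell and 7 did not pass (6 higher and 0 lower adjusted over the list alone; camera adjusted p = 7.46e-06, and adjusted p = 0.0332 with an estimated correlation), with Pim1 at 1.82 ± 0.14 and Gadd45b at 1.16 ± 0.10. Of 22 adhesion and matrix remodelling genes, 7 rose, 1 fell and 14 did not pass (10 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.000105, and adjusted p = 0.0229 with an estimated correlation). The leukocyte adhesion molecule Icam1 rose by 1.96 ± 0.22 and Vcam1 by 1.47 ± 0.21.

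Among 20 cytokines and growth factors in wild-type cells at 1 h, 6 rose, 2 fell and 12 did not pass (9 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00175, and adjusted p = 0.0942 with an estimated correlation). Il6 rose by 2.90 ± 0.27 and Lif by 2.36 ± 0.14, while Il11 fell (-1.45 ± 0.19). Of 14 MAPK phosphatases and feedback genes, 4 rose, 0 fell and 10 did not pass (6 higher and 0 lower adjusted over the list alone; camera adjusted p = 4.86e-06, and adjusted p = 0.115 with an estimated correlation), with Dusp1 at 1.74 ± 0.14 and Dusp5 at 1.46 ± 0.14. Of 19 acute phase and inflammatory effectors, 4 rose, 0 fell and 15 did not pass (4 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0265, and adjusted p = 0.107 with an estimated correlation). The mean of this list was 0.12 and its median -0.02, and its adjusted p was 0.0617 without wild-type 1 h replicate 2 and 0.0884 without wild-type unstimulated replicate 1. Ch25h, which encodes cholesterol 25-hydroxylase, rose by 2.04 ± 0.21. Transcripts that fell included Ret, which encodes a receptor tyrosine kinase (-2.37 ± 0.14), Zfp87 (-2.39 ± 0.17), Pkp1 (-2.26 ± 0.36), Sema4f (-2.18 ± 0.34) and Aldh1a3, a gene of retinoic acid synthesis (-2.16 ± 0.22). Il1r1, the gene of the IL-1 receptor, had a log2 fold change of 0.07 ± 0.15 (adjusted p = 0.822), Myd88 0.28 ± 0.18 (adjusted p = 0.404) and Traf6 -0.03 ± 0.19 (adjusted p = 0.949).

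At 1 h in wild-type cells, 930 of the 12427 genes tested passed an adjusted p of 0.05 in limma, 363 higher and 567 lower, and 206 of them changed at least 2-fold. With each array centred on its median the split was 638 higher and 406 lower. Leaving out wild-type 1 h replicate 1 gave 483 genes, and leaving out replicate 2 of that group gave 410. The unstimulated control was grown for 4 h, so time in culture differed along with IL-1b in this comparison.

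After 4 h, wild-type cells were compared with the same unstimulated control. Cxcl2 reached a signal of 4685 ± 532 (SD, n = 2), a log2 fold change of 8.65 ± 0.16 (SE, n = 2 arrays per group; adjusted p = 8.09e-16). Il6, an inflammatory cytokine gene, went from 10.9 ± 3.61 to 1612 ± 64.6 (SD, n = 2), a rise of 6.43 ± 0.27. Icam1 rose by 5.25 ± 0.22, the acute phase gene Saa3 by 4.69 ± 0.39, and Gbp3, an interferon-inducible guanylate-binding protein gene, by 4.82 ± 0.24. Id4, which encodes an inhibitor of helix-loop-helix transcription factors, fell (-2.38 ± 0.14), as did the chemokine receptor gene Cxcr4 (-2.28 ± 0.28) and Rgcc (-2.19 ± 0.24). The median over all genes tested was -0.12, so rises and falls stand against that value.

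Among 17 chemokines in wild-type cells at 4 h, 13 rose, 0 fell and 4 did not pass (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.41e-31, and adjusted p = 0.00326 with an estimated correlation). Cxcl1 rose by 6.65 ± 0.25, Ccl20 by 5.61 ± 0.24, Ccl2 by 5.35 ± 0.17 and Cxcl3 by 4.57 ± 0.40. For the 19 acute phase and inflammatory effectors, 14 rose, 0 fell and 5 did not pass (16 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.01e-21, and adjusted p = 0.00326 with an estimated correlation). Steap4, a metalloreductase gene, rose by 4.63 ± 0.35, Ch25h by 3.80 ± 0.21 and Lcn2, which encodes an iron-binding lipocalin, by 3.55 ± 0.50. For adhesion and matrix remodelling, 14 rose, 1 fell and 7 did not pass (17 higher and 2 lower adjusted over the list alone; camera adjusted p = 4.67e-19, and adjusted p = 0.00326 with an estimated correlation). Mmp10 and Mmp9, both matrix metalloproteinase genes, rose by 3.67 ± 0.22 and 2.51 ± 0.25, and Vcam1 by 3.02 ± 0.21. Of the 15 NF-kB genes, 10 rose, 0 fell and 5 did not pass (11 higher and 0 lower adjusted over the list alone; camera adjusted p = 5.65e-16, and adjusted p = 0.00326 with an estimated correlation), with Zc3h12a at 5.41 ± 0.38, Nfkbie at 3.61 ± 0.21, Tnfaip3 at 3.47 ± 0.14 and Nfkbia at 1.85 ± 0.11. Of the cytokines and growth factors, 10 rose, 0 fell and 10 did not pass (12 higher and 0 lower adjusted over the list alone; camera adjusted p = 3.15e-14, and adjusted p = 0.007 with an estimated correlation). Lif rose by 4.08 ± 0.14, Csf2 by 3.68 ± 0.46 and Tnfsf11, the gene of RANK ligand, by 3.18 ± 0.21.

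The survival genes at 4 h in wild-type cells divided as follows: 9 rose, 0 fell and 4 did not pass (9 higher and 0 lower adjusted over the list alone; camera adjusted p = 7.02e-12, and adjusted p = 0.009 with an estimated correlation). The death receptor gene Fas rose by 2.43 ± 0.12 and the co-stimulatory receptor gene Cd40 by 1.42 ± 0.25. Of 21 interferon-stimulated genes, 6 rose, 0 fell and 15 did not pass (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.31e-06, and adjusted p = 0.0158 with an estimated correlation). Gbp2 rose by 2.91 ± 0.23 and Trim21 by 1.66 ± 0.17. Immediate early genes at 4 h numbered 10 that rose and 0 that fell (15 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.7e-10, and adjusted p = 0.0911 with an estimated correlation), with Ier3 at 1.74 ± 0.10 and Fos at 0.26 ± 0.28 (adjusted p = 0.6; 0.00598 without wild-type unstimulated replicate 2). Of 26 Hox genes, the transcription factors of body axis position, 0 rose, 12 fell and 14 did not pass (0 higher and 15 lower adjusted over the list alone; camera adjusted p = 1.97e-05, and adjusted p = 0.0229 with an estimated correlation). Their mean was -0.53 against the median of -0.12 over all genes, and the list stayed lower under quantile normalization and median centring. Hoxa5 fell (-1.13 ± 0.18). Il1r1 rose by 1.62 ± 0.15, while Il1rap (-0.14 ± 0.18, adjusted p = 0.68) and Irak2 (-0.39 ± 0.20, adjusted p = 0.226) did not pass.

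At 4 h in wild-type cells 1498 genes were called, 578 higher and 920 lower, and 368 of them changed at least 2-fold. Median centring turned the split to 1164 higher and 436 lower. Without wild-type 4 h replicate 2 the count was 962.

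Wild-type cells were also compared between 4 h and 1 h of IL-1b. Saa3 was higher at 4 h by 4.97 ± 0.39 (SE, n = 2 arrays per group; adjusted p = 1.39e-07), Steap4 by 4.81 ± 0.35, Il6 by 3.53 ± 0.27 and Icam1 by 3.29 ± 0.22. Fosb (-4.55 ± 0.48), Fos (-4.11 ± 0.28), Nr4a1 (-3.13 ± 0.20), a nuclear receptor gene, and Zfp36 (-3.02 ± 0.16) were lower at 4 h. Hpgd, which encodes a prostaglandin-degrading enzyme, was lower too (-3.21 ± 0.22). The difference for Cxcl1 was 0.01 ± 0.25 (adjusted p = 0.977) and for Cxcl2 0.25 ± 0.16 (adjusted p = 0.322).

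Of the immediate early genes, 0 rose, 16 fell and 15 did not pass between 1 h and 4 h (0 higher and 18 lower adjusted over the list alone; camera adjusted p = 4.3e-12, and adjusted p = 0.0781 with an estimated correlation). Acute phase and inflammatory effectors moved the other way: 13 rose, 0 fell and 6 did not pass (14 higher and 0 lower adjusted over the list alone; camera adjusted p = 2.91e-13, and adjusted p = 0.004 with an estimated correlation). The cytokines and growth factors gave 11 rises and 0 falls (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.41e-07, and adjusted p = 0.0229 with an estimated correlation), among them Tnfsf11 at 2.28 ± 0.21 and Tslp at 2.12 ± 0.16. Of the chemokines 11 rose, 1 fell and 5 did not pass (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.7e-09, and adjusted p = 0.0103 with an estimated correlation), with Ccl11 at 2.43 ± 0.30 and Cxcl16 at 2.40 ± 0.25. Of the adhesion and matrix genes 14 rose, 2 fell and 6 did not pass (15 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.81e-09, and adjusted p = 0.00608 with an estimated correlation). In all 2363 genes were called between the time points, 1044 higher and 1319 lower at 4 h, and with median centring the split was 1289 higher and 966 lower. The count was 1463 without wild-type 1 h replicate 1, 1373 without wild-type 1 h replicate 2 and 1571 without wild-type 4 h replicate 2.

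In kinase-dead cells the response at 1 h was set against unstimulated kinase-dead cells. Fos went from 104 ± 7.85 to 1654 ± 60.6 (SD, n = 2), a rise of 3.89 ± 0.28 (SE, n = 2 arrays per group; adjusted p = 4.75e-07). The growth-factor-responsive transcription factor genes Egr3, Egr2 and Egr1 rose by 2.99 ± 0.13, 1.76 ± 0.16 and 1.40 ± 0.09, and Nr4a1 by 2.17 ± 0.20. Btg2, an antiproliferative gene, rose by 1.70 ± 0.13, Edn1, the gene of the vasoconstrictor endothelin-1, by 1.61 ± 0.22, and Errfi1, which encodes an inhibitor of the EGF receptor, by 1.46 ± 0.10. Cxcl2 rose by 1.25 ± 0.16, from 0.90 ± 0.28 to 13.2 ± 1.77 (SD, n = 2), and these signals lie under the filter threshold of 25.5. Il6 had a log2 fold change of 0.80 ± 0.27 (adjusted p = 0.132; 0.0421 without kinase-dead unstimulated replicate 2). Nfkbia had 0.35 ± 0.11 (adjusted p = 0.107; 0.00786 and 0.00781 without wild-type unstimulated replicates 1 and 2). The other 4 Nfkbia probe sets tested were called higher (0.83, 0.63, 0.64 and 0.53; adjusted p of 0.00396, 0.00412, 0.0135 and 0.00447).

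Of the 31 immediate early genes in kinase-dead cells at 1 h, 20 rose, 0 fell and 11 did not pass (21 higher and 0 lower adjusted over the list alone; camera adjusted p = 4.61e-31, and adjusted p = 0.0158 with an estimated correlation). Of the 14 MAPK phosphatases and feedback genes, 6 rose, 0 fell and 8 did not pass (6 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.64e-10, and adjusted p = 0.0453 with an estimated correlation). The phosphatase genes Dusp5 and Dusp1 rose by 1.39 ± 0.14 and 1.23 ± 0.14. Of the 17 chemokines, 4 rose, 0 fell and 13 did not pass (4 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.387, and adjusted p = 0.527 with an estimated correlation), with a mean of 0.00 and a median of -0.15. Ccl2 rose by 0.89 ± 0.17, but its adjusted p was 0.101 without kinase-dead unstimulated replicate 2 and 0.083 without kinase-dead 1 h replicate 2. Of 21 genes of the ATF4 and unfolded protein responses, 0 rose, 4 fell and 17 did not pass (1 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.000105, and adjusted p = 0.171 with an estimated correlation), with Psat1, a gene of serine synthesis, at -0.73 ± 0.10. Camera also called higher the cytokine, acute phase, survival, p53 target, and TGF-beta and YAP target lists. With an estimated correlation their camera adjusted p was 0.136, 0.136, 0.165, 0.0602 and 0.19. All of these calls but that of the p53 targets ended when some single arrays were left out. NF-kB genes did not pass camera but were higher by fry (adjusted p = 0.00114). At 1 h in kinase-dead cells 407 genes were called, 193 higher and 214 lower, and 74 changed at least 2-fold. Wild-type arrays enter this count only through the shared estimate of spread. With only the compared groups in the fit, 587 genes were called here and 409 in wild-type cells at 1 h. The count in the main fit moved with single arrays. It was 643 and 645 without wild-type unstimulated replicates 1 and 2, 235 and 94 without kinase-dead unstimulated replicates 1 and 2, and 122 and 108 without kinase-dead 1 h replicates 1 and 2. The actin 3' to 5' ratio was 2.85 in the control and 2.42 at 1 h. With this ratio as a covariate, a fit chosen after the data were seen, 169 genes were called.

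After 4 h of IL-1b, chemokine transcripts were higher in kinase-dead cells than in their unstimulated control. Ccl2 went from 56.8 ± 5.37 to 1499 ± 1.27 (SD, n = 2), a rise of 4.54 ± 0.17 (SE, n = 2 arrays per group; adjusted p = 2.48e-11). Cxcl1 rose by 5.01 ± 0.25, Cxcl2 by 4.02 ± 0.16, Ccl7 by 3.90 ± 0.16 and Ccl20 by 2.93 ± 0.24. Nfkbiz rose by 2.79 ± 0.09, Nfkbie by 1.99 ± 0.21, Nfkbia by 1.15 ± 0.11, Icam1 by 1.77 ± 0.22 and Rgs16, a regulator of G-protein signalling, by 1.81 ± 0.15. Il6 had a log2 fold change of 0.94 ± 0.27 (adjusted p = 0.131; 0.0326 without kinase-dead unstimulated replicate 2). Ptgs2, the gene of cyclooxygenase 2, had 0.45 ± 0.12 (adjusted p = 0.0941; 0.0255 and 0.026 without wild-type unstimulated replicates 1 and 2, 0.0312 without kinase-dead unstimulated replicate 2). Fos was 2.29-fold higher (adjusted p = 0.0718; 0.000827 and 0.000951 without wild-type unstimulated replicates 1 and 2).

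Of the 17 chemokines in kinase-dead cells at 4 h, 6 rose, 0 fell and 11 did not pass (6 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.92e-14, and adjusted p = 0.00543 with an estimated correlation). Of the 15 NF-kB genes, 5 rose, 0 fell and 10 did not pass (10 higher and 0 lower adjusted over the list alone; camera adjusted p = 5.65e-16, and adjusted p = 0.00326 with an estimated correlation). Cytokines and growth factors had 4 rises and 0 falls (9 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.32e-08, and adjusted p = 0.018 with an estimated correlation). For the survival genes 3 rose, 0 fell and 10 did not pass (7 higher and 0 lower adjusted over the list alone; camera adjusted p = 3.12e-07, and adjusted p = 0.0229 with an estimated correlation). For the acute phase and inflammatory effectors 2 rose, 0 fell and 17 did not pass (4 higher and 0 lower adjusted over the list alone; camera adjusted p = 4.64e-06, and adjusted p = 0.0158 with an estimated correlation). For the immediate early genes 4 rose, 0 fell and 27 did not pass (18 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.45e-11, and adjusted p = 0.0804 with an estimated correlation), with Ier3 at 1.29 ± 0.10. At 4 h 77 genes were called in kinase-dead cells, 55 higher and 22 lower, and 28 changed at least 2-fold. With median centring the split was 73 higher and 15 lower. With only the compared groups in the fit, 304 genes were called here and 663 in wild-type cells at 4 h. Wild-type arrays enter the count of the main fit only through the shared estimate of spread. Leaving out single arrays gave 315 and 316 genes (wild-type unstimulated replicates 1 and 2), 45 and 45 (wild-type 1 h replicates 1 and 2), 51 (kinase-dead unstimulated replicate 2), 46 and 49 (kinase-dead 1 h replicates 1 and 2), and 28 and 30 (kinase-dead 4 h replicates 1 and 2). The actin 3' to 5' ratio was 2.85 in the control and 2.49 at 4 h. With this ratio as a covariate 40 genes were called.

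**Figure D1:**
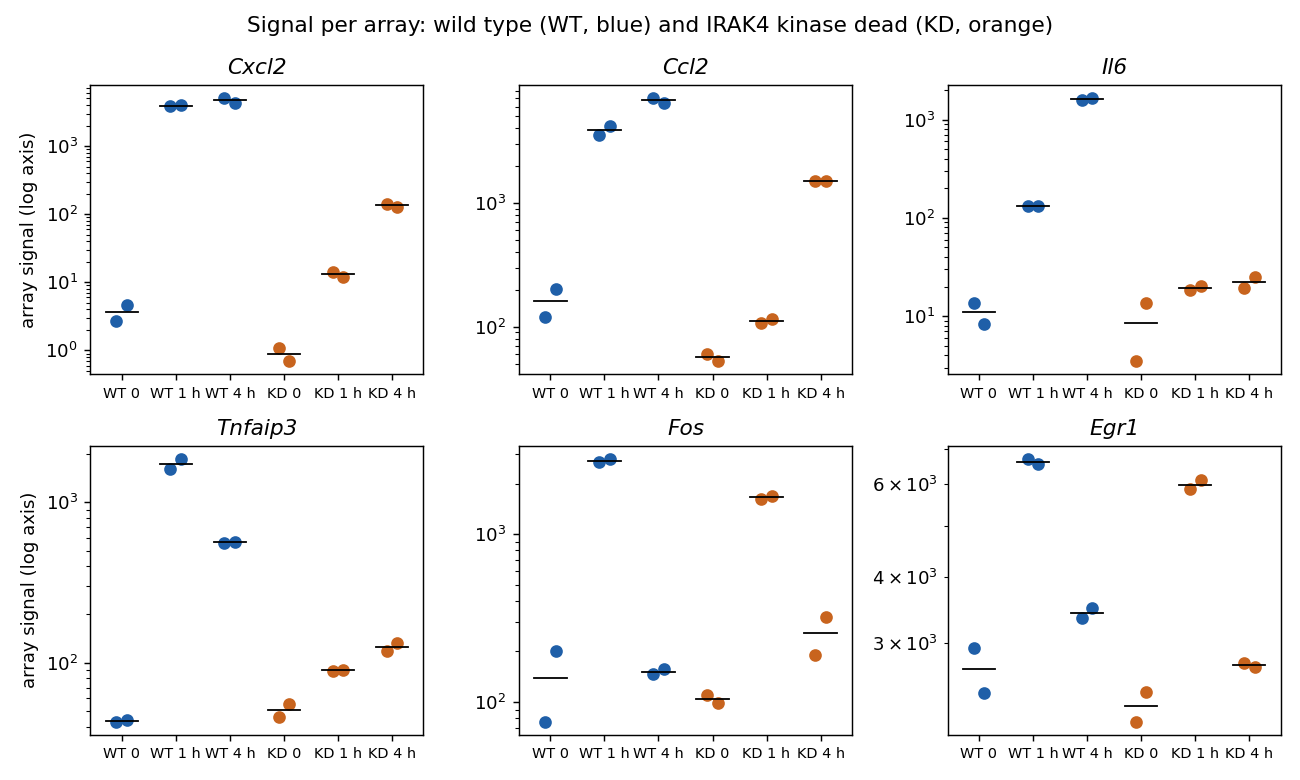
Array signal (log axis) of 6 transcripts in each of the 12 arrays; points are arrays, lines are group means, WT is wild type, KD is kinase dead, and 0 marks unstimulated cells. Il6 reached a mean of 1612 in wild-type and 22.4 in kinase-dead cells after 4 h, and Egr1 a mean of 6627 and 5990 after 1 h.

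The difference between the genotypes in their response was tested directly, as the kinase-dead log2 fold change minus the wild-type log2 fold change. At 1 h this difference was -7.15 ± 0.23 for Cxcl2 (SE, n = 2 arrays per group; adjusted p = 5.12e-12), -5.34 ± 0.35 for Cxcl1, -4.31 ± 0.33 for Ccl20 and -3.66 ± 0.24 for Ccl2. Responses were also smaller in kinase-dead cells for Tnfaip3 (-4.35 ± 0.20), Nfkbiz (-2.95 ± 0.13), Nfkbia (-1.69 ± 0.16) and Irf1, the gene of an interferon regulatory factor (-3.57 ± 0.31). Zfp36 (-2.0 ± 0.22) and Btg2 (-1.22 ± 0.18) differed the same way. For Fos the difference was -0.47 ± 0.40 (adjusted p = 0.811; a difference of 0.19, not called, without wild-type unstimulated replicate 1), for Egr1 0.08 ± 0.13 (adjusted p = 0.91), for Egr3 0.08 ± 0.19 (adjusted p = 0.953) and for Nr4a1 -0.63 ± 0.28 (adjusted p = 0.556).

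Of the 17 chemokines, 6 had a smaller response in kinase-dead cells at 1 h and 0 a larger one (0 higher and 9 lower adjusted over the list alone; camera adjusted p = 5.88e-23, and adjusted p = 0.00326 with an estimated correlation). Of the 15 NF-kB genes, 4 had a smaller response and 0 a larger one (1 higher and 6 lower adjusted over the list alone; camera adjusted p = 1.42e-10, and adjusted p = 0.00543 with an estimated correlation). Immediate early genes numbered 4 with a smaller response, 1 with a larger one and 26 that did not pass (1 higher and 10 lower adjusted over the list alone; camera adjusted p = 1.16e-08, and adjusted p = 0.121 with an estimated correlation). MAPK phosphatases and feedback genes gave a camera adjusted p of 0.666. Responses differed for 61 genes at 1 h, 43 of them more negative and 18 more positive in kinase-dead cells. The count was 103 without wild-type unstimulated replicate 1, 38 without wild-type 1 h replicate 2, and 35 and 40 without kinase-dead 1 h replicates 1 and 2. With the actin 3' to 5' ratio, which was 2.85 in the kinase-dead and 2.41 in the wild-type control, as a covariate it was 42. The call on Il6 (-2.10 ± 0.39, adjusted p = 0.0154) was lost without wild-type unstimulated replicate 2, either wild-type 1 h or 4 h array, kinase-dead unstimulated replicate 2 or either kinase-dead 1 h array, with adjusted p of 0.0512 to 0.0981.

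At 4 h the response difference was -5.49 ± 0.39 for Il6 (SE, n = 2 arrays per group; adjusted p = 2.99e-07). It was -4.63 ± 0.23 for Cxcl2, -4.57 ± 0.56 for Cxcl3, -4.08 ± 0.52 for Ccl5, -4.02 ± 0.34 for Gbp3, -3.67 ± 0.55 for Saa3 and -3.48 ± 0.31 for Icam1. Id4 (2.12 ± 0.19) and Cxcr4 (2.24 ± 0.40), which fell in wild-type cells, had more positive responses in kinase-dead cells. For Ccl7 the difference was -0.21 ± 0.22 (adjusted p = 0.68). For Ccl2 it was -0.81 ± 0.24 (adjusted p = 0.0787; 0.000618 without wild-type unstimulated replicate 2; 0.0341 with median centring). The median over all genes was 0.11.

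Of the 19 acute phase and inflammatory effectors, 10 had a smaller response in kinase-dead cells at 4 h and 9 did not pass (1 higher and 11 lower adjusted over the list alone; camera adjusted p = 5.76e-15, and adjusted p = 0.00326 with an estimated correlation). The chemokines gave 10 smaller responses of 17 (0 higher and 11 lower adjusted over the list alone; camera adjusted p = 7.45e-20, and adjusted p = 0.00326 with an estimated correlation), and adhesion and matrix genes 9 of 22 (0 higher and 10 lower adjusted over the list alone; camera adjusted p = 2.61e-14, and adjusted p = 0.00326 with an estimated correlation), with Mmp10 at -3.02 ± 0.32. Cytokines and growth factors gave 5 of 20 (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 3.61e-08, and adjusted p = 0.019 with an estimated correlation), with Lif at -2.93 ± 0.20. NF-kB genes gave 5 of 15 (0 higher and 5 lower adjusted over the list alone; camera adjusted p = 1.87e-06, and adjusted p = 0.0155 with an estimated correlation), with Nfkbie at -1.62 ± 0.29. Interferon-stimulated genes gave 5 of 21 (0 higher and 5 lower adjusted over the list alone; camera adjusted p = 2.67e-05, and adjusted p = 0.019 with an estimated correlation), with Gbp2 at -2.69 ± 0.32. Hox genes differed the other way, with 5 of 26 more positive in kinase-dead cells (9 higher and 0 lower adjusted over the list alone; camera adjusted p = 3.36e-06, and adjusted p = 0.019 with an estimated correlation), under quantile normalization and median centring as well. Responses differed for 377 genes at 4 h, 181 more positive and 196 more negative in kinase-dead cells. With median centring the split was 121 and 343. The count was 717 without wild-type unstimulated replicate 1, 226 without kinase-dead unstimulated replicate 2, and 216 and 220 without kinase-dead 4 h replicates 1 and 2. With the actin 3' to 5' ratio (2.85 and 2.41 in the controls) as a covariate it was 373. The call on Cxcl1 (-1.64 ± 0.35, adjusted p = 0.0142) was lost without wild-type 4 h replicate 1 (adjusted p = 0.065), kinase-dead unstimulated replicate 1 (0.0699) or kinase-dead 4 h replicate 2 (0.0797). The other 2 Cxcl1 probe sets tested had smaller responses that were called (-2.25 and -1.87; adjusted p of 9.74e-06 and 5.66e-05).

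**Figure D2:**
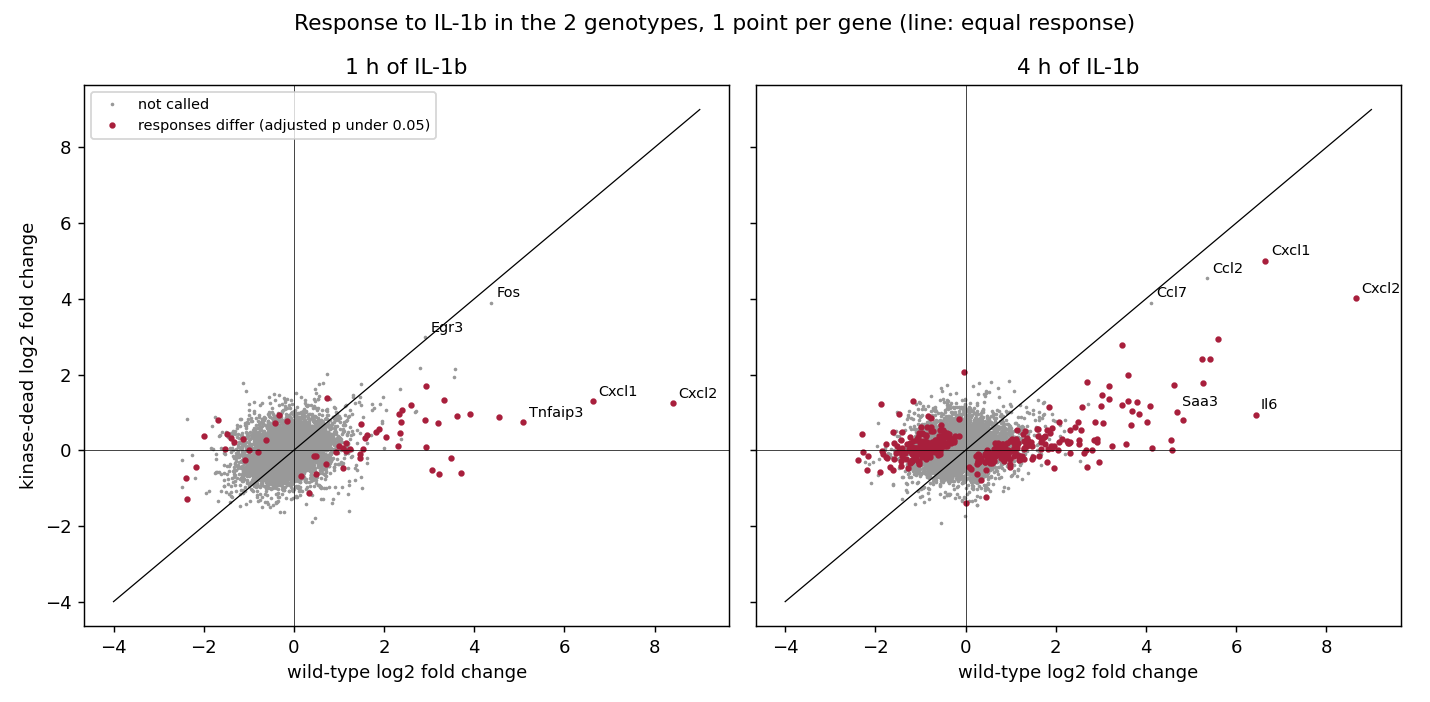
Log2 fold change in kinase-dead cells (vertical axis) against wild-type cells (horizontal axis) after 1 h and 4 h of IL-1b, 1 point per gene, with the line of equal responses. Red points are the 61 genes at 1 h and the 377 genes at 4 h whose responses differed, and Cxcl2, with wild-type changes of 8.40 and 8.65, lies far under the line at both times.

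The size of the kinase-dead response was also measured over the 8 lists of IL-1 responsive classes, which were set before the data were examined. With no filter the ratio of the kinase-dead to the wild-type mean was 0.424 at 1 h and 0.425 at 4 h. In the main fit 151 members were tested, which passed the filter on these arrays and could enter by a high wild-type signal alone. Their mean log2 fold change at 1 h was 0.865 in wild-type and 0.357 in kinase-dead cells, a ratio of 0.412 ± 0.0535 (SD over the choices of 1 array per group), and 98 of the 151 members had the lower value in kinase-dead cells. At 4 h the means were 1.31 and 0.551, a ratio of 0.422 ± 0.039, with 115 members lower. At 1 h the ratio was 0.675 ± 0.1 for immediate early genes, 0.0956 ± 0.025 for NF-kB genes, 0.000556 ± 0.0631 for chemokines. It was 0.543 ± 0.115 for cytokines, 0.222 ± 0.111 for adhesion and matrix genes and 0.306 ± 0.316 for survival genes. MAPK phosphatases and feedback genes had the higher mean in kinase-dead cells at 1 h (0.619 against 0.422, a ratio of 1.47 ± 0.602), although 8 of 14 members were lower there. Acute phase and inflammatory effectors had the higher mean too (0.152 against 0.119, with 9 of 19 members lower, a ratio of 1.27 ± 5.74). At 4 h it was 0.887 ± 0.384 for immediate early genes, 0.786 ± 0.592 for MAPK phosphatases and feedback genes, 0.59 ± 0.026 for NF-kB genes and 0.475 ± 0.141 for survival genes. It was 0.424 ± 0.00834 for chemokines, 0.362 ± 0.024 for cytokines, 0.263 ± 0.0432 for acute phase and inflammatory effectors and 0.25 ± 0.0145 for adhesion and matrix genes.

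Of the 363 genes higher in wild-type cells at 1 h, 106 were also called higher in kinase-dead cells, against 5.64 for independent lists (two-sided Fisher's exact p = 6.11e-115). Of the 567 lower genes, 122 were shared, against 9.76 (Fisher's exact p = 2.27e-109). At 4 h 41 of the 578 higher genes were shared, against 2.56 (Fisher's exact p = 1.39e-43), and 1 of the 920 lower genes, against 1.63 (p = 1). Only 22 genes were called lower in kinase-dead cells at 4 h (116 and 119 without wild-type unstimulated replicates 1 and 2). Called or not, the sign in kinase-dead cells was the same for 328 (90.4%) of the higher and 515 (90.8%) of the lower genes at 1 h. At 4 h it was the same for 436 (75.4%) of the higher and 653 (71%) of the lower genes. The genotypes had separate controls, but their tests used the same estimate of spread per gene. The calls are therefore not independent, and Fisher's test does not allow for this. Both controls were grown for 4 h, so time in culture may enter the changes shared at 1 h.

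**Figure D3:**
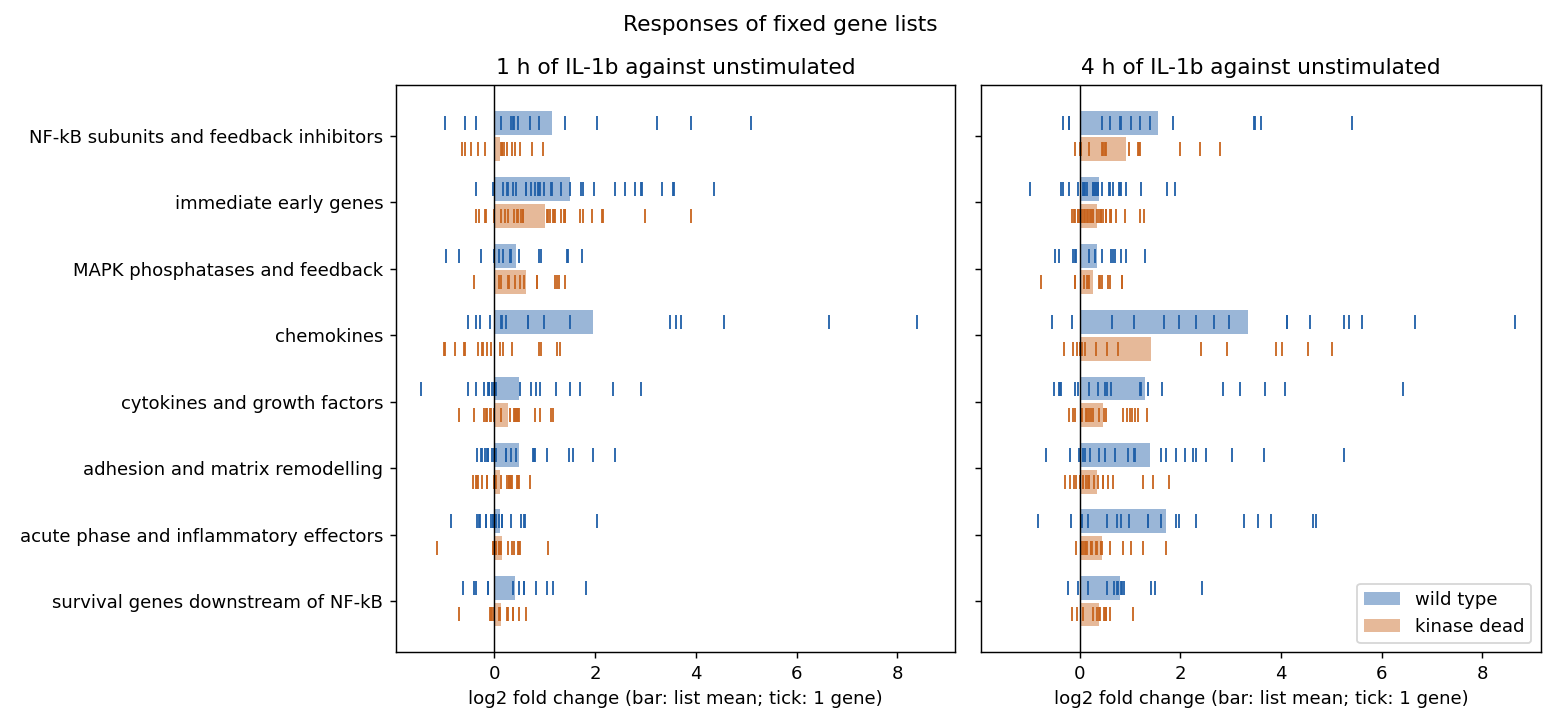
Mean log2 fold change (bars) and single members (ticks) of the 8 fixed lists after 1 h and 4 h of IL-1b, in wild-type (blue) and kinase-dead (orange) cells. Chemokines had means of 1.97 and 0.00 at 1 h and 3.35 and 1.42 at 4 h, and immediate early genes 1.5 and 1.01 at 1 h.

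Unstimulated kinase-dead and wild-type cells were compared next. Xist, the RNA of X inactivation, was lower in kinase-dead cells (-7.23 ± 0.39; SE, n = 2 arrays per group; adjusted p = 2.07e-09), and the Y-linked genes Eif2s3y, Kdm5d and Uty were higher by 6.96 ± 0.19, 5.88 ± 0.21 and 3.64 ± 0.34. The signal of Xist was 2643 ± 17.9 in wild-type and 11.8 ± 12.8 in kinase-dead cells (SD, n = 2). Hoxd13, a gene of limb and posterior patterning, was lower (-5.13 ± 0.20), as were the matrix metalloproteinase genes Mmp13 (-3.32 ± 0.19) and Mmp3 (-3.31 ± 0.17) and the matrix gene Thbs4 (-3.75 ± 0.22). Col14a1, a fibril-associated collagen gene, was higher (3.36 ± 0.15), as was the transcription factor gene Foxd1 (2.73 ± 0.18). Of the IL-1 receptor genes, Il1r1 (-1.16 ± 0.15) and Il1rap (-0.87 ± 0.18) were lower in kinase-dead cells, calls that ended when all probe sets of a gene were averaged. Myd88 (-0.01 ± 0.18, adjusted p = 0.973) and Irak1 (0.26 ± 0.18, adjusted p = 0.38) did not pass. Of the other 3 Irak1 probe sets 1 was called higher (0.91, adjusted p = 0.00334).

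Of the 22 adhesion and matrix remodelling genes in unstimulated cells, 1 was higher in kinase-dead cells, 15 were lower and 6 did not pass (2 higher and 15 lower adjusted over the list alone; camera adjusted p = 3.78e-10, and adjusted p = 0.00543 with an estimated correlation). Cytokines and growth factors gave 1 higher and 11 lower of 20 (1 higher and 11 lower adjusted over the list alone; camera adjusted p = 7.72e-07, and adjusted p = 0.0249 with an estimated correlation), with Tnfsf11 at -3.01 ± 0.21 and Il11 at -2.60 ± 0.19. Immediate early genes gave 0 higher and 17 lower (0 higher and 22 lower adjusted over the list alone; camera adjusted p = 2e-11, and adjusted p = 0.0804 with an estimated correlation), with Sgk1 at -1.43 ± 0.10 and Egr3 at -1.12 ± 0.13. Chemokines gave 2 higher and 6 lower (2 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.0027, and adjusted p = 0.0788 with an estimated correlation), with Ccl2 at -1.35 ± 0.17 and Cxcl1 at -1.31 ± 0.25. Of 15 macrophage markers, 8 were higher, 0 were lower and 7 did not pass (10 higher and 0 lower adjusted over the list alone; camera adjusted p = 3.25e-08, and adjusted p = 0.009 with an estimated correlation), with the complement gene C1qb at 2.23 ± 0.27 and Mpeg1 at 2.21 ± 0.42. Camera gave adjusted p of 0.876 for endothelial, 0.875 for epithelial, 0.615 for skeletal and cardiac muscle, 0.329 for neural and glial, 0.934 for adipocyte and 0.506 for cartilage and bone markers. By fry the neural and glial markers were higher in kinase-dead cells (adjusted p = 0.013), with 2 of 10 members called higher and 0 lower.

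Of the 26 Hox genes tested, 8 were higher and 6 lower in unstimulated kinase-dead cells (12 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.562), with a mean of -0.05 and a median of 0.46. The 11 genes of paralog groups 1 to 5 had a median difference of 1.01 and the 10 genes of groups 9 to 13 a median of -1.31, and both kept their sign under quantile normalization (1.07 and -1.23) and median centring (1.05 and -1.28). Hoxb5 was higher by 2.38 ± 0.23 and Hoxb3 by 1.64 ± 0.12, while Hoxd10 was lower (-2.01 ± 0.12). In all 1786 genes were called between the unstimulated genotypes, 919 higher and 867 lower, and 530 differed at least 2-fold. The count was 1061 without kinase-dead unstimulated replicate 1 and 1174 without replicate 2 of that group. Unstimulated kinase-dead cells had an actin 3' to 5' ratio of 2.85 against 2.41 in wild-type cells. With this ratio as a covariate 1214 genes were called.

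**Figure D4:**
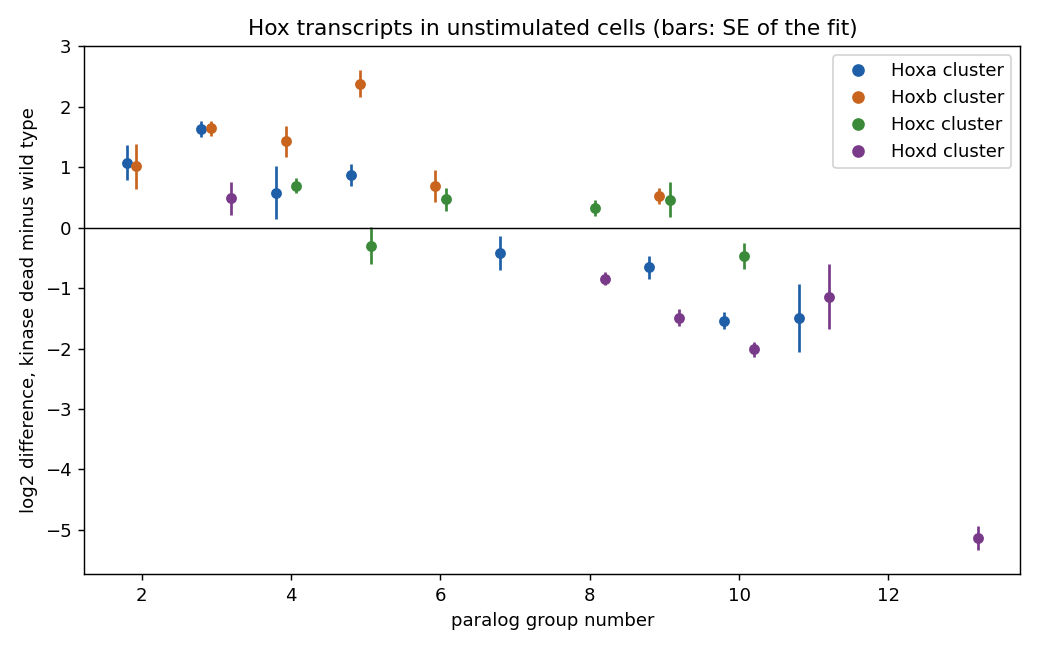
Log2 difference between unstimulated kinase-dead and wild-type cells (points, with the SE of the fit as bars, n = 2 arrays per group) of 26 Hox genes against paralog group number, with a colour for each cluster. The median was 1.01 in groups 1 to 5 and -1.31 in groups 9 to 13, and Hoxd13 lay at -5.13.

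Over the 3 conditions together, with 6 arrays of each genotype, differences of the same kind were found. Xist (-7.58 ± 0.25; SE, n = 6 arrays per genotype; adjusted p = 9.46e-13), Cxcl5 (-5.51 ± 0.42), Hoxd13 (-5.01 ± 0.15) and Mmp13 (-4.26 ± 0.24) were lower in kinase-dead cells. The adhesion gene Cadm1 (2.93 ± 0.13) and Rgs5 (3.09 ± 0.07), a regulator of G-protein signalling, were higher. Of the adhesion and matrix remodelling genes, 1 was higher, 17 were lower and 4 did not pass (1 higher and 17 lower adjusted over the list alone; camera adjusted p = 6.55e-15, and adjusted p = 0.0421 with an estimated correlation). Of the macrophage markers, 10 were higher, 0 were lower and 5 did not pass (11 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.37e-07, and adjusted p = 0.00543 with an estimated correlation). Of the 10 neural and glial markers, 3 were higher and 1 was lower (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.157, and 0.000353 by fry). Fabp7, a gene of radial glia, stood at 2.59 ± 0.12, the stem cell gene Sox2 at 1.44 ± 0.15, Nes at 0.57 ± 0.15 and Map2 at -0.64 ± 0.19. This comparison called 3422 genes, 1984 higher and 1438 lower in kinase-dead cells, 616 of them by at least 2-fold. It includes the IL-1b-treated arrays, so genes with different responses enter it too.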

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

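All tests of technical and biological explanations in this part were chosen after the results were seen. The tests of response differences and the count of other splits of the arrays were set before the data were examined.

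Genes whose response to IL-1b differed between the genotypes numbered 61 at 1 h and 377 at 4 h. At 1 h the gene lists with a response difference had mean differences of -1.97 (chemokines), -1.03 (NF-kB genes), -0.487 (immediate early genes), -0.372 (adhesion and matrix remodelling), -0.297 (cholesterol synthesis) and -0.279 (survival genes). The adjusted p with an estimated correlation was 0.121 for immediate early genes, 0.0804 for survival genes and 0.0106 for cholesterol synthesis. Smaller differences were -0.242 for interferon-stimulated genes, -0.0766 for fibroblast matrix genes and -0.0715 for smooth muscle and myofibroblast markers, and with an estimated correlation their adjusted p = 0.136, 0.527 and 0.36. The interferon call was lost without either wild-type unstimulated array, wild-type 1 h replicate 2, wild-type 4 h replicate 1, kinase-dead unstimulated replicate 2 or kinase-dead 1 h replicate 1 (adjusted p of 0.0506 to 0.149). The fibroblast matrix call was lost without wild-type unstimulated replicate 2, wild-type 1 h replicate 1, either kinase-dead unstimulated array or either kinase-dead 1 h array (0.058 to 0.726). The smooth muscle call was lost without replicate 2 of the wild-type unstimulated, wild-type 1 h, kinase-dead unstimulated or kinase-dead 1 h group (0.106 to 0.374).

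At 4 h the lists had mean differences of -1.93 (chemokines), -1.27 (acute phase and inflammatory effectors), -1.04 (adhesion and matrix remodelling), -0.833 (cytokines and growth factors), -0.639 (NF-kB genes), -0.617 (interferon-stimulated genes), -0.427 (survival genes) and 0.576 (Hox genes). Hypoxia and glycolysis genes (-0.188, adjusted p = 0.107 with an estimated correlation), ATF4 and unfolded protein response genes (-0.161, 0.355 with an estimated correlation) and fibroblast matrix genes (-0.0872, 0.482 with an estimated correlation) differed less. The ATF4 call was lost without kinase-dead unstimulated replicate 2 (adjusted p = 0.23) or wild-type 4 h replicate 1 (0.109). The fibroblast call was lost without wild-type unstimulated replicate 2 (0.312), wild-type 4 h replicate 1 (0.152) or kinase-dead 4 h replicate 1 (0.0838).

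Named genes with a response difference at 1 h were Cxcl2 (-7.15), Cxcl1 (-5.34), Tnfaip3 (-4.35), Ccl20 (-4.31), Zc3h12a (-3.86), Cxcl5 (-3.70), Ccl2 (-3.66), Irf1 (-3.57), Nfkbiz (-2.95), Zfp36 (-2.0), Nfkbia (-1.69), Pim1 (-1.33), Btg2 (-1.22) and Gadd45b (-1.18). Bcl6b (1.71) and Zfp87 (1.66) had more positive responses in kinase-dead cells. At 4 h they were Il6 (-5.49), Cxcl2 (-4.63), Cxcl3 (-4.57), Gbp6 (-4.28), Ccl5 (-4.08), Gbp3 (-4.02), Saa3 (-3.67), Icam1 (-3.48), Mmp10 (-3.02), Lif (-2.93), Ccl20 (-2.67) and Tnfaip3 (-2.29). Cxcr4 (2.24), Id4 (2.12), Hoxa3 (1.47) and Hoxa10 (1.11) had more positive responses in kinase-dead cells at 4 h.

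Probe sets without a single gene name, outside the comparisons of the report, also changed when every probe set was tested. Of 4410 such probe sets, those called numbered 381 (wild type, 1 h), 212 (wild type, 4 h), 97 (kinase dead, 1 h), 16 (kinase dead, 4 h), 19 (response difference, 1 h), 49 (response difference, 4 h), 602 (wild type, 4 h against 1 h), 367 (unstimulated genotypes) and 870 (genotypes over all conditions).

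Of 31 immediate early genes, 23 rose at 1 h in wild-type and 20 in kinase-dead cells, and their mean response difference was -0.487 (camera adjusted p = 1.16e-08, and 0.121 with an estimated correlation). If bright probe sets were saturated, dim members would show the genotype difference and bright members would hide it. The median response difference of the 11 dim members minus that of the 12 bright members was -0.986 (permutation p = 0.0058), so saturation may hide part of a difference. Dim members also had the larger wild-type rise (median 2.4 against 1.23), so the test cannot tell saturation from the size of the rise. The members were split by the wild-type 1 h signal, which itself enters the difference. All 12 bright members had lower 1 h signals in kinase-dead cells (median log2 ratio -0.697), but the median ratio before stimulation was already -0.552. The highest wild-type 1 h mean among bright members, 6630, lay under the highest signal measured, 17066. Handling or time in culture cannot be told apart from IL-1b in the kinase-dead mean rise of 1.01, since no unstimulated 1 h group was analysed here. A route to these genes that needs no IRAK4 kinase activity stays open and was not tested.

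Chemokines and NF-kB genes rose less in kinase-dead cells. Compression by the pseudocount as the whole cause is argued against for 12 of the 23 members called in wild-type cells at 4 h. These 12 lay at or above the filter threshold in both unstimulated groups. Without a pseudocount their median response difference was -0.679 (-0.754 with it), all 12 below 0, and their mean -1.18 (-1.23 to -1.12 over 16 choices of 1 array per group). All 23 were chosen by their wild-type rise, which is subtracted in the difference, so that choice pushes the values below 0. Over the members tested of the lists as set beforehand, 15 of 17 chemokines and 12 of 15 NF-kB genes had the lower change in kinase-dead cells at 4 h. These members passed the filter on these arrays and could enter by a high wild-type signal alone, which favours this direction. For the other 11 members, with a lower unstimulated signal, equal folds with the pseudocount would give a median of -0.349 where -2.67 was measured, and without it the median was -2.19 (-3 to -1.95 over the choices), with 9 members below 0 and Ccl7 and Bcl3 above. Scaling of the kinase-dead arrays would lower all genes, and the median response difference over all genes at 4 h was 0.105. Each array was already scaled to the same trimmed mean, which limits such a shift, so this median cannot decide. Both lists kept their calls of smaller responses at 4 h under quantile normalization and median centring. A part played by the pseudocount and the array's own floor under those 11 signals stays open. Lower receptor transcripts before stimulation (Il1r1 at -1.16 in unstimulated kinase-dead cells) cannot be told apart from the loss of kinase activity, since 1 dose was used and the cells differ in both. The cultures also differed before stimulation in Xist, Y-linked, Hox and macrophage marker transcripts, with 1786 genes called in all. None of these differences can be told apart from the genotype as a source of the smaller responses, so that the genotype named in the design stays open.

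The genotypes differed before stimulation in 1786 genes. Of the calls, 95.9% lay on other chromosomes than X and Y. Only 398 genes tested lay on X or Y, so most calls had to lie elsewhere, and this share decides nothing about sex. Of the X and Y genes 18.3% were called, and of the other genes 14.3%. Effects of sex on genes of other chromosomes were not tested. Cells from different parts of the embryo body may contribute: the Hox differences fell with paralog number (Spearman rho -0.851 and Pearson r -0.803 across 26 genes, which are not independent; permutation p = 1e-05, the smallest the permutations can give). Macrophages in the kinase-dead cultures may contribute too: 15 of 15 markers tested were higher, 8 of them called, with Lyz2 at 98.1 and 283, Ctss at 52.2 and 210 and C1qb at 24.3 and 141 in wild-type and kinase-dead cells, while Cd53 stayed at 249.9 and 256.5. Of these 15 markers 7 lay at or above the filter threshold in wild-type cells and 0 are in another list. The rest could enter the test through kinase-dead arrays where they are high, which can raise the count of higher markers. Xist and the Y-linked transcripts differed as between female wild-type and male kinase-dead cells, so sex cannot be told apart from the genotype. Litter, cell line and RNA quality (1214 genes called with the actin ratio as a covariate) stay open with the genotype too.

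Other splits of the 12 arrays into 6 and 6 were counted for the comparison over all conditions. Of 100 splits drawn from 462, 1 called as many genes as the real one, which was the real split itself (3422 genes). The highest other split called 25. In those splits the genotype difference stays in the spread, which lowers their counts. The count shows that the arrays group by genotype label. It cannot tell the genotype from other differences between the wild-type and kinase-dead cultures.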

How the results depend on the processing

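The alternatives were set before the data were examined, except 3 that were chosen after the data were seen. Without X and Y genes the genotype counts were 1702 (unstimulated) and 3263 (all conditions). With the actin 3' to 5' ratio as a covariate the counts were 1149 (wild type 1 h), 1735 (wild type 4 h), 169 (kinase dead 1 h), 40 (kinase dead 4 h), 42 (response difference 1 h), 373 (response difference 4 h), 2526 (wild type 4 h against 1 h), 1214 (unstimulated genotypes) and 3015 (genotypes over all conditions); those of the kinase-dead responses moved by more than 1.5 times, and since the ratio varies little within the kinase-dead control, this fit cannot separate the ratio from that group. Without both kinase-dead unstimulated arrays they were 879 (wild type 1 h), 1414 (wild type 4 h), 2282 (wild type 4 h against 1 h) and 2640 (genotypes over all conditions), and comparisons that use these arrays cannot be made. The cause of further moves was not tested, except where the setting itself is stricter or tests fewer or more features. Leaving out an array outside a comparison changes only the estimate of spread. In the other alternatives counts of genes moved by more than 1.5 times as follows. Without the variance trend they were 466 (wild type 1 h), 57 (kinase dead 1 h), 22 (kinase dead 4 h), 19 (response difference 1 h) and 156 (response difference 4 h). With every probe set as a feature they were 1800 (wild type 1 h), 637 (kinase dead 1 h), 99 (response difference 1 h), 3979 (wild type 4 h against 1 h), 2929 (unstimulated genotypes) and 6247 (genotypes over all conditions). With the mean of a gene's probe sets they were 554 (wild type 1 h), 939 (wild type 4 h), 152 (kinase dead 1 h), 38 (kinase dead 4 h), 34 (response difference 1 h), 175 (response difference 4 h) and 1458 (wild type 4 h against 1 h). With the groups compared alone in the fit they were 409 (wild type 1 h), 663 (wild type 4 h), 304 (kinase dead 4 h) and 1082 (unstimulated genotypes). At 2-fold or more they were 206 (wild type 1 h), 368 (wild type 4 h), 74 (kinase dead 1 h), 28 (kinase dead 4 h), 202 (response difference 4 h), 569 (wild type 4 h against 1 h), 530 (unstimulated genotypes) and 616 (genotypes over all conditions). At an adjusted p under 0.01 they were 412 (wild type 1 h), 738 (wild type 4 h), 126 (kinase dead 1 h), 32 (kinase dead 4 h), 38 (response difference 1 h), 179 (response difference 4 h), 1330 (wild type 4 h against 1 h), 1019 (unstimulated genotypes) and 2222 (genotypes over all conditions). Array weights gave 921 (wild type 4 h), 643 (kinase dead 1 h) and 201 (kinase dead 4 h), and no filter gave 271 (kinase dead 1 h) and 49 (kinase dead 4 h). The other pseudocounts, the floor, the stricter filter, quantile normalization, median centring and the robust variance model moved no count beyond 1.5 times. Leaving out 1 array at a time gave 410 to 1015 (wild type 1 h), 962 to 1553 (wild type 4 h), 94 to 645 (kinase dead 1 h), 28 to 316 (kinase dead 4 h), 35 to 103 (response difference 1 h), 216 to 717 (response difference 4 h), 1373 to 2761 (wild type 4 h against 1 h), 1061 to 1995 (unstimulated genotypes), 2962 to 3297 (genotypes over all conditions), 97 to 108 called list tests, and response ratios of 0.363 to 0.462 (1 h) and 0.389 to 0.455 (4 h); the group left with 1 array was assumed to vary like the others.

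The list tests called numbered 104 with the preset and 52 with an estimated correlation. The response ratio was 0.583 at 1 h as a ratio of medians over members and 0.377 at 4 h with a pseudocount 4 times larger. Fibroblast matrix genes turned from lower to higher response differences under quantile normalization, with adjusted p = 0.74 (1 h) and 0.844 (4 h). With the mean of probe sets Itga8 turned to 0.082 at 4 h in wild-type cells and Hoxa3 to 0.059 between 1 h and 4 h, neither called, and the cause was not tested. Over 661 named gene results, 588 of them called, 18430 alternative values held 16852 with the same sign and the same side of the threshold, 1466 that lost the call, 37 that gained it, 2 reversed and 73 that changed sign without a call in either fit. With the replicate number as a block the counts were 922 (wild type 1 h), 1480 (wild type 4 h), 382 (kinase dead 1 h), 86 (kinase dead 4 h), 64 (response difference 1 h), 369 (response difference 4 h), 2335 (wild type 4 h against 1 h), 1743 (unstimulated genotypes) and 3315 (genotypes over all conditions), with 105 list tests, none beyond 1.5 times. The numbers did not pair the arrays: correlations of same-numbered deviations were -0.05 to 0.1 over 15 pairs of groups, and 8 of 12 arrays lay closest to their own number. Low signals limit what can be seen, since a change under the filter threshold of 25.5 is compressed by the pseudocount of 8.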

Other observations

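Both hypotheses in this part were tested on the data in which they were noticed, and their tests were chosen after the results were seen.

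Cholesterol synthesis genes differed between time points and between genotypes. Of 16 tested, 4 rose, 0 fell and 12 did not pass (5 higher and 0 lower adjusted over the list alone; camera adjusted p = 4.92e-06, and adjusted p = 0.016 with an estimated correlation) in wild-type cells at 1 h, with Insig1, a sterol-sensing regulator, at 0.50 ± 0.07 (SE, n = 2 arrays per group). Between 1 h and 4 h 0 rose, 8 fell and 8 did not pass (0 higher and 9 lower adjusted over the list alone; camera adjusted p = 3.62e-05, and adjusted p = 0.0218 with an estimated correlation), with the sterol carrier gene Stard4 at -1.07 ± 0.12. Both comparisons also differ in time in culture, which was not separated from IL-1b. In wild-type cells at 4 h, against a control grown equally long, the list did not pass camera but was lower by fry (adjusted p = 0.00289). In unstimulated kinase-dead cells 0 were higher, 12 were lower and 4 did not pass (0 higher and 13 lower adjusted over the list alone; camera adjusted p = 6.22e-11, and adjusted p = 0.00543 with an estimated correlation), with Nsdhl at -1.31 ± 0.14. Their response difference at 1 h had 0 single members called (0 higher and 6 lower adjusted over the list alone), and the list's camera adjusted p was 2.44e-07.

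Smooth muscle and p53 lists differed between the unstimulated genotypes. Of 12 smooth muscle and myofibroblast markers, 4 were higher in kinase-dead cells, 0 were lower and 8 did not pass (5 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.000606, and adjusted p = 0.165 with an estimated correlation), with Synpo2 at 1.28 ± 0.18 (SE, n = 2 arrays per group). Of 14 p53 targets, 6 were higher, 0 were lower and 8 did not pass (8 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.000606, and adjusted p = 0.0783 with an estimated correlation), with Perp at 0.89 ± 0.14 and Pmaip1 at 0.63 ± 0.10.

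Transcripts with Zfp symbols, most of which name zinc finger proteins, were frequent among the falls at 1 h in wild-type cells. The pattern was first seen with a wider set of Zfp, Zkscan, Zscan and Zbtb symbols (343 tested), counted in each of the 4 responses, and then narrowed to Zfp followed by a number (289 tested), which includes Zfp36. In wild-type cells at 1 h 44 of the 289 were called lower (odds ratio 3.99, Fisher's exact adjusted p = 1.09e-11 over 16 tests), and 53 of the 343 (odds ratio 4.11). Leaving out each array in turn gave odds ratios of 2.92 to 5.45 for the 289, with Fisher's exact p of 4.69e-07 or less. In kinase-dead cells 14 of the 289 were called lower (odds ratio 3.04, Fisher's exact adjusted p = 0.00258), and 15 of the 343 (odds ratio 2.73, adjusted p = 0.00354). That result rests on 214 genes called lower, a number that ran from 27 to 337 when 1 array was left out. The odds ratio for the 289 was 1.56 (Fisher's exact p = 0.334, 112 genes called lower) and 3.38 (p = 0.13, 27 genes) without kinase-dead unstimulated replicates 1 and 2. It was 2.44 (Fisher's exact p = 0.136, 55 genes) without kinase-dead 1 h replicate 2, 2.62 to 3.46 with p under 0.05 in the other 9 fits, and 3.71 (p = 0.0079, 75 genes) with the actin ratio as a covariate. At 4 h the odds ratio for falls was 0.878 in wild-type cells, and 0 of the 289 were among the 22 genes called lower in kinase-dead cells. Whether called or not, the median kinase-dead log2 change at 1 h was -0.154 for the 289 against -0.0101 for other genes. It was -0.194 to -0.128 against -0.0171 to -0.00569 when 1 array was left out, so the direction did not depend on a single array. Camera gave p = 0.00134 (0.000539 to 0.0154 over the 12 fits), but with an estimated correlation p = 0.0529 (0.0314 to 0.143, under 0.05 in 2 of 12). In wild-type cells the latter was 0.0129 (0.00448 to 0.0274). The transcripts as a set moved down in both genotypes, and whether this exceeds what correlated genes would give in kinase-dead cells stays open. These tests were not run under quantile normalization or median centring. With median centring 406 genes were called lower in wild-type cells at 1 h, against 567 in the main fit. Genes of a family are not independent, and a difference in time in culture between the 1 h cells and the control was not separated from IL-1b.

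Genes that still rose at 4 h in kinase-dead cells may be those that wild-type cells raised early. Of 578 genes higher in wild-type cells at 4 h, 129 were also higher at 1 h, and 31 of these (24%) were called higher in kinase-dead cells at 4 h, against 10 of the other 449 (2.23%). Within quartiles of the wild-type rise, of which 3 of 4 could be used, the common odds ratio was 10.2 (95% interval 4.49 to 24.9, exact p = 3.43e-10). The early genes had larger wild-type rises (median 1.04 against 0.672), and a size difference within quartiles stays open. Only 55 genes were called higher in kinase-dead cells at 4 h, and 22 to 199 when 1 array was left out. In these 12 fits the shares ran from 15.3% to 38% for the early and from 0.703% to 12.8% for the other genes. The common odds ratio was 3.36 to 18.2, with exact p of 4.8e-05 or less, and lowest without wild-type unstimulated replicates 1 (3.36) and 2 (3.90). With the actin ratio as a covariate it was 14.5. Whether or not they were called in kinase-dead cells, the median ratio of the kinase-dead to the wild-type log2 change was 0.369 for the early and 0.18 for the other genes, but 0.0908 and 0.105 without wild-type unstimulated replicate 1. The wild-type calls at 1 h and 4 h share their control arrays, and genes are not independent. With median centring the genes called higher in wild-type cells numbered 638 at 1 h and 1164 at 4 h. The odds ratio was not taken on that scaling.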
